A study of Mus musculus with 24 samples.

How the data were processed

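The data were 24 libraries of stranded mRNA (TruSeq Stranded mRNA, per the labels' protocols) from tissue labelled as back left brain, 3 for each combination of genotype (dKO or WT), sex and day (10 or 20). The authors deposited 1 table of raw counts per gene for each library. Reads were handled with STAR 2.5.2b and HTSeq on the genome build GRCm38.p5, per the submitters' processing notes; which tool made the counts and which gene annotation was used are not given there. Each table held 50686 genes and 4 entries that name no gene (unmapped, multimapping, no-feature and ambiguous reads). Of its count columns the one for the reverse strand (column 4) was used, since the forward strand held 5.22 to 7.46% as many counts in 23 libraries. In those 23 libraries no-feature reads were 41.7 to 47.5% of reads, unmapped reads 7.65 to 11.0%, multimapping reads 4.77 to 5.94% and ambiguous reads 0.589 to 1.05%, and the 10 most abundant genes held 7.20 to 12.7% of gene counts. Symbols, types and positions came from GENCODE M21 on GRCm38, which matched 50462 gene identifiers and left 224 without a match.

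Gene counts per library were 9.19 to 44.7 M (M, mega, as in CPM) in 23 libraries, where 1 count is 0.0224 to 0.109 CPM. The library labelled dKO male day 10 replicate 3 held 45964 gene counts, with 32.1% no-feature and 32.0% unmapped reads, 33 counts of Xist and 7 of 4 Y-linked genes (Kdm5d, Eif2s3y, Uty, Ddx3y). It was kept in the tests as planned and left out of CPM levels, which was decided after its total was seen. No library was a copy of another. Sex was checked with Xist and the same 4 Y-linked genes, whose sum was 308 to 443 CPM in males and 0.116 to 0.899 CPM in females.

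The tests were made in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (21006 genes), libraries were scaled by TMM, and all 24 libraries were fitted with 1 mean per group (8 groups) by glmQLFit with robust estimation. Each contrast was tested by glmQLFTest, two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with calls at an adjusted p under 0.05. The contrasts were dKO against WT in each sex at each day and over both sexes at each day, the genotype by day and genotype by sex interactions, WT day 20 against day 10, and WT males against females. Levels are CPM with TMM factors. Shares of WT for Pank1 and Pank2 are fitted ratios with 95% confidence intervals from the SE. Log2 CPM used a prior count of 2.

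Gene lists were written before the data were examined: 50 lists with 995 genes, of which 3 tested symbols were not in the annotation. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry; p-values were adjusted over the 50 lists. Counts of called list members are given over all genes tested and adjusted over the list alone. A list's score in a library is its mean log2 CPM. The size of the day 20 change in each sex was compared by exact permutation of sex within genotype, two-sided. Nearness to Pank1 or Pank2 means within 5 Mb.

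Named genes followed a rule. For both sexes at each day it took Pank1 to Pank4, the 8 greatest rises and 8 greatest falls among called genes with a mean of at least 1 CPM over the 12 libraries of that day and the same sign in both sexes, and up to 4 members of each list described by p. For 1 sex at 1 day it took the 3 rising and 3 falling genes with the smallest p, for each interaction the 5 genes with the smallest p, and for WT day 20 against day 10 the 5 greatest rises and falls. For WT males against females it took up to 10 genes by p. Of the genes that the rule names, list members that were not called are not given, and 1 called list member is not reported here. Genes named for gene families in the closing section were chosen after their values were seen.

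The test was tried on simulated data, drawn from each gene's mean and spread without correlation between genes, with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold at each day. In that order it recovered 67.2, 88.1 and 98.5% of changed genes for both sexes at day 20, with 22 false among 225 calls (9.78%). For both sexes at day 10 it recovered 59.7, 83.6 and 92.4%, with 14 false among 205 calls (6.83%). For females it recovered 44.8, 73.1 and 89.4% at day 10 (7 false of 166, 4.22%) and 41.8, 79.1 and 92.4% at day 20 (14 of 178, 7.87%). For males it recovered 40.3, 65.7 and 83.3% at day 10 (3 of 142, 2.11%) and 49.3, 77.6 and 93.9% at day 20 (8 of 176, 4.55%). Of the 50 lists, 2 were shifted by 0.5 on the log2 scale, and both and 0 others were called at either day.

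Alternatives were RLE size factors, no filter, a stricter filter (mean of at least 1 CPM), the unstranded column, edgeR's earlier dispersion estimate, DESeq2 1.42.0, limma-voom, 1 surrogate variable from svaseq (sva 3.50.0), glmTreat at 1.2-fold, fitting only the groups compared, and leaving out each replicate in turn. After the data were seen, more were added: leaving out the library of 45964 counts, leaving it out with dKO male day 10 replicate 2, voom with quality weights, 1 surrogate variable without the library of 45964 counts, and the scores of 2 regional lists (granule cells, Hox) as covariates without it. A fit with replicates as blocks was not run, since the labels give no replicate numbers and replicates here are numbered in the order of deposition. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.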

Results

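RNA was measured by stranded mRNA sequencing in a piece of tissue labelled as back left brain from C57BL/6 mice. The knockout mice were Pank1-/- Syn-Pank2-/- (dKO below) and the controls were wild type (WT); what Syn stands for, and which exons were removed, are not given in the sources used here. Pank1 and Pank2 encode pantothenate kinases, which catalyse the opening step of coenzyme A (CoA) synthesis. Genotype, sex and day (10 or 20) gave 8 groups of 3 libraries, 24 in all. Gene counts per library ran from 9.19 to 44.7 M in 23 libraries (M, mega). By group, they were 9.19 to 44.7 M in WT at day 10, 10.8 to 20.0 M in dKO at day 10, 18.7 to 42.5 M in WT at day 20 and 15.9 to 27.3 M in dKO at day 20. In those 23 libraries 1 count stood for 0.0224 to 0.109 CPM (counts per 1 M), and such limits cover counting error only. The library labelled dKO male day 10 replicate 3 held 45964 gene counts. It gave Xist at 718 CPM and 4 Y-linked genes at 152 CPM together, whereas the 23 others matched their labelled sex, with Xist at 669 to 1262 CPM in females and 0.610 to 2.44 CPM in males. It was kept in the tests and left out of the CPM values, so dKO at day 10 has n = 5 in those. CPM values are means ± SD, log2 changes are ± SE and stand in brackets after a gene's name where no other quantity is named, positions are on GRCm38 (GENCODE M21), and a gene was called at an adjusted p under 0.05 among 21006 tested. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples.

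The first question was whether the targeted genes differed between the genotypes. Pank1 fell at both days, and Pank2 fell at day 20 by a smaller margin and was not called at day 10. Pank3, which was not targeted, also fell at day 20. Pank1 (ENSMUSG00000033610, chromosome 19, 34806940 to 34879455, minus strand) was at 8.19 ± 0.68 CPM in dKO (n = 5) against 22.9 ± 1.65 in WT (n = 6) at day 10, or 36.2% of WT (32.4 to 40.6), a log2 change of -1.46 ± 0.08 (adjusted p = 1.46e-11). At day 20 it was at 7.55 ± 0.46 CPM against 22.9 ± 2.37 (n = 6 each), or 33.2% of WT (29.9 to 36.7), with a log2 change of -1.59 ± 0.08 (adjusted p = 7.55e-14). Pank2 (ENSMUSG00000037514, chromosome 2, 131262495 to 131299188, plus strand) was at 50 ± 3.02 CPM in dKO and 52.9 ± 3.40 in WT at day 10, or 93.5% of WT (86.3 to 101; log2 -0.10 ± 0.06, adjusted p = 0.323). At day 20 Pank2 was at 42.3 ± 3.21 CPM against 56.8 ± 3.28, or 74.3% of WT (68.9 to 80.1), with a log2 change of -0.43 ± 0.06 (adjusted p = 1.5e-06). These counts cover whole genes and so do not test the part that was deleted. Among the other pantothenate kinase genes, Pank3 (chromosome 11, 35769484 to 35791285) was at 132 ± 12.6 CPM in dKO against 174 ± 8.92 in WT at day 20 (log2 -0.40 ± 0.05, adjusted p = 7.95e-07) and did not pass at day 10 (log2 0.04, adjusted p = 0.655). Pank4 was called at neither day (log2 -0.07 at day 10, adjusted p = 0.565, and 0.11 at day 20, adjusted p = 0.192).

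At day 20, dKO was compared with WT over both sexes to ask which transcripts differ between knockout and control at the later day. Genes of the glucocorticoid and fasting response rose, among them Fkbp5, Hif3a and Plin4. Genes of the unfolded protein response in the endoplasmic reticulum fell, among them Manf, Pdia4 and Hsp90b1. Interferon-response genes fell as well. Lists of microglial and of heme and erythroid genes were lower too, but with adjusted p = 0.0902 and adjusted p = 0.0577 with an estimated correlation between genes. The single genes with the greatest rises included Matn1, which encodes a cartilage matrix protein, and Plin4, which encodes a coat protein of lipid droplets.

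In all, 8188 of 21006 genes (39.0%) were called at day 20, 4080 higher and 4108 lower in dKO. The median size of change among them was 0.41 on the log2 scale, and 1040 changed more than 2-fold. Calls numbered 4404 in DESeq2 and 2941 when a change above 1.2-fold was required.

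Matn1 (ENSMUSG00000040533, chromosome 4, 130944385 to 130955475) was at 26.6 ± 5.77 CPM in dKO and 0.363 ± 0.201 in WT (n = 6 each), a 73.7-fold difference and a log2 change of 6.20 ± 0.17 (adjusted p = 9.63e-18). Plin4 (chromosome 17, 56100591 to 56109803) was at 66.7 ± 32.8 CPM against 2.27 ± 0.346, a 28.6-fold difference (log2 4.84 ± 0.34, adjusted p = 1.97e-08). The immune receptor gene Pilrb2 rose by 4.76 ± 0.34 and Hao1, which encodes a peroxisomal hydroxyacid oxidase, by 4.46 ± 0.58 on the log2 scale, both from low levels (2.74 ± 1.03 CPM against 0.0926 ± 0.0673 for Pilrb2, and 2.15 ± 2.45 against 0.0587 ± 0.0442 for Hao1). The greatest log2 change, 8.06 ± 0.73, was that of Gm13394, a processed pseudogene at 41.0 ± 15.1 CPM in dKO and 0.138 ± 0.0913 in WT. The predicted genes Gm9008 (4.59 ± 0.58) and Gm17120 (4.28 ± 0.37) and the processed pseudogene Gm6969 (4.46 ± 1.01) also rose. Reads of pseudogenes can come from near-identical copies elsewhere, so their source is uncertain. In the other direction, the erythrocyte genes Slc4a1 (-3.66 ± 0.50), Hbb-bt (-3.42 ± 0.38) and Hba-a2 (-2.68 ± 0.37) fell. Hbb-bt (chromosome 7, 103812524 to 103813996) was at 4.46 ± 1.21 CPM in dKO against 47.6 ± 12.8 in WT (adjusted p = 2.18e-06). The microglial receptor gene Fcrls (chromosome 3, 87250758 to 87263738) was at 1.51 ± 0.901 CPM against 10.1 ± 1.34, a log2 change of -2.93 ± 0.14 (adjusted p = 7.55e-14). The proliferation genes Top2a (-2.76 ± 0.55) and Mki67 (-2.67 ± 0.48) fell, from 3.22 ± 1.03 and 5.65 ± 2.12 CPM in WT to 0.449 ± 0.138 and 0.832 ± 0.276 in dKO. The protease gene Ctsc fell by 2.76 ± 0.61, but its WT libraries parted: 3 lay between 68.8 and 118 CPM, and 3 between 6.06 and 9.63 CPM, within the dKO range of 5.80 to 11.2. The processed pseudogene Gm12941 fell by 3.11 ± 0.29. Some sizes moved with the alternatives while the calls held: with the unstranded column Plin4 rose by 2.71 and Gm17120 by 1.72, and Gm12941 fell by 1.39 and Mki67 by 1.59, and without WT male day 20 replicate 1 Ctsc fell by 1.46.

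**Figure D1:**
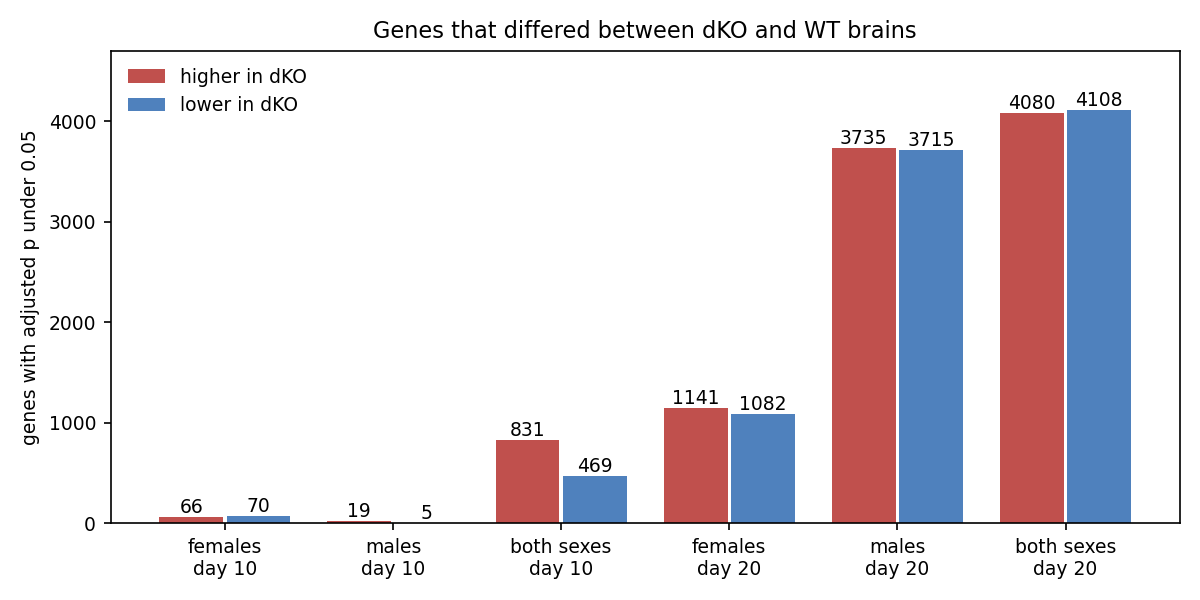
Bars give the number of genes called higher and lower in dKO for each comparison of dKO with WT (adjusted p under 0.05 of 21006 tested). Both sexes at day 20 gave 8188, against 1300 at day 10.

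**Figure D2:**
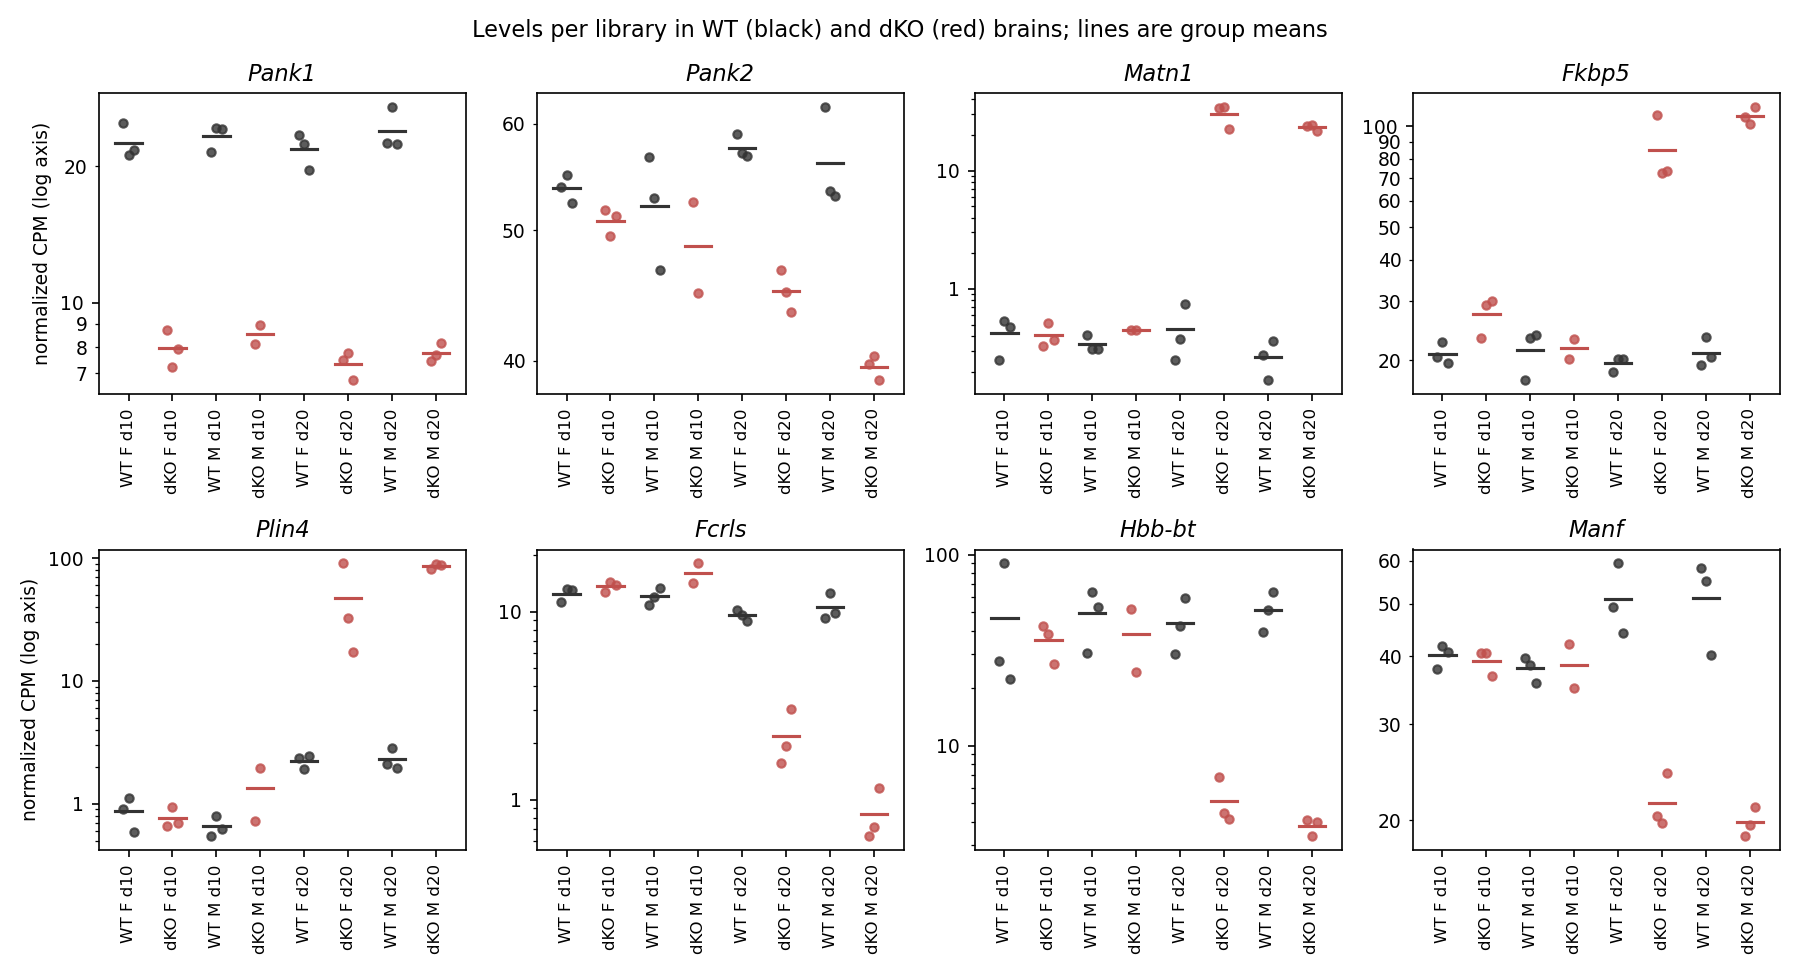
Level of 8 genes in each library in CPM on a log axis, by genotype, sex and day (WT black, dKO red, lines at group means). Matn1, Fkbp5 and Plin4 sat higher and Pank1, Fcrls, Hbb-bt and Manf lower in dKO at day 20.

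Of 50 lists of genes chosen before the data were examined, 21 passed at day 20 (adjusted p under 0.05 by camera with a preset correlation between genes). With the correlation estimated from the data, 4 lists were called: glucocorticoid and fasting response, unfolded protein response, interferon response, and hemostasis and acute phase. The glucocorticoid and fasting list had 22 of 24 genes higher and 0 lower (22 and 0 adjusted over the list alone), a median log2 change of 1.47 and adjusted p = 3.13e-41 (adjusted p = 0.000232 with an estimated correlation). Within it Fkbp5, which encodes a cochaperone of the glucocorticoid receptor, rose from 20.3 ± 1.67 to 96.2 ± 18.2 CPM (log2 2.24 ± 0.10, adjusted p = 1.77e-13). Hif3a, which encodes a subunit of the hypoxia-inducible factors, rose from 14.3 ± 2.82 to 73.0 ± 10.8 CPM (log2 2.36 ± 0.11, adjusted p = 2.87e-13). The kinase gene Map3k6 rose by 2.72 ± 0.15 and the sulfotransferase gene Sult1a1 by 1.67 ± 0.12 on the log2 scale. The hemostasis and acute-phase list had 9 of 10 genes higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.03 and adjusted p = 1.88e-07 (adjusted p = 0.0129 with an estimated correlation). Its strongest members were Lcn2 (3.04 ± 0.37), which encodes an iron-siderophore carrier, Pla2g3 (1.89), the transcription factor gene Cebpd (1.23) and the interleukin receptor gene Il1r1 (0.72). Some genes stand in more than 1 list, so the lists are not independent. Lcn2, and Per1, Foxo1 and Irs2 named below for the clock and insulin lists, are also members of the glucocorticoid and fasting list. The circadian clock list had 9 of 17 genes higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.53 and adjusted p = 2.55e-07, but adjusted p = 0.124 with an estimated correlation. Nr1d1 rose by 0.97, Per1 by 0.96, Cry2 by 0.64 and Bhlhe40 by 0.60.

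The unfolded protein response list had 0 of 19 genes higher and 16 lower (0 and 16 adjusted over the list alone), a median log2 change of -0.77 and adjusted p = 2.98e-23 (adjusted p = 0.0313 with an estimated correlation). The disulfide isomerase genes Pdia4 (-1.39 ± 0.09) and Pdia6 (-1.09 ± 0.09), the secreted factor gene Manf (-1.31 ± 0.08, adjusted p = 4.01e-11) and the chaperone gene Hsp90b1 (-0.96 ± 0.07) all fell. The interferon list had 1 of 21 genes higher and 17 lower (2 and 17 adjusted over the list alone), with a median of -0.86 and adjusted p = 2.95e-07 (adjusted p = 0.0313 with an estimated correlation). Ifi44 (-1.66), Ifi27 (-0.86), the transcription factor gene Irf9 (-0.58) and the antigen-presentation gene B2m (-0.46) fell within it. The heme and erythroid list had 1 of 18 genes higher and 12 lower (1 and 12 adjusted over the list alone), with a median of -0.63 and adjusted p = 2.21e-07, but adjusted p = 0.0577 with an estimated correlation. Within it the hemoglobin gene Hba-a1 fell by 2.51 and the heme synthesis gene Uros fell by 0.63. The immediate early gene list had 3 of 22 genes higher and 12 lower (3 and 12 adjusted over the list alone), with a median of -0.45 and adjusted p = 0.000925, but adjusted p = 0.136 with an estimated correlation. Nr4a3 (-2.0), Arc (-1.34), Homer1 (-0.46) and Jun (-0.44) fell.

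Among the metabolic lists at day 20, sterol genes moved together and most others held members going both ways. The cholesterol synthesis list had 0 of 25 genes higher and 18 lower (0 and 18 adjusted over the list alone), with a median of -0.34 and adjusted p = 3.82e-10, but adjusted p = 0.124 with an estimated correlation. The pathway enzyme genes Hmgcs1 (-0.84), Idi1 (-0.80), Cyp51 (-0.76) and Sqle (-0.61) fell. The list of nuclear-encoded respiratory chain genes had 0 of 44 higher and 22 lower (0 and 23 adjusted over the list alone), with a median of -0.15 and adjusted p = 9.99e-05, but adjusted p = 0.711 with an estimated correlation. The cytochrome c gene Cycs (-0.65) fell with Uqcrb (-0.38), Ndufb3 (-0.37) and Atp5g1 (-0.33). The CoA synthesis and turnover list, which holds Pank1 and Pank2 themselves, had 2 of 15 genes higher and 7 lower (2 and 7 adjusted over the list alone), with a median of -0.06 and adjusted p = 0.00752, but adjusted p = 0.0534 with an estimated correlation. Enpp1, which encodes a nucleotide pyrophosphatase, fell by 0.95. The tricarboxylic acid cycle list had 2 of 28 genes higher and 13 lower (2 and 14 adjusted over the list alone; median -0.12, adjusted p = 0.0288), but adjusted p = 0.727 with an estimated correlation. The dehydrogenase genes Ogdh (-0.39) and Sdhc (-0.29) fell, while Idh2 rose by 0.54 and the pyruvate dehydrogenase kinase gene Pdk2 by 0.47. The fatty acid synthesis list had 4 of 20 genes higher and 8 lower (4 and 8 adjusted over the list alone; median -0.09, adjusted p = 0.0394), but adjusted p = 0.553 with an estimated correlation. The elongase genes Elovl6 (-0.74) and Elovl5 (-0.57) and the desaturase genes Scd2 (-0.47) and Fads1 (-0.31) fell. The list of amino acid and one-carbon catabolism to acyl-CoA had 10 of 22 genes higher and 4 lower (11 and 4 adjusted over the list alone; median 0.15, adjusted p = 0.0313), but adjusted p = 0.278 with an estimated correlation. Aldh6a1, Mccc2 and Mccc1, all of which act on branched-chain amino acids or their products, rose by 0.73, 0.55 and 0.41, and Bckdhb fell by 0.37. The insulin and IGF list had 5 of 17 genes higher and 4 lower (5 and 4 adjusted over the list alone; median 0.09, adjusted p = 0.027), but adjusted p = 0.248 with an estimated correlation. The binding-protein gene Igfbp3 rose by 1.32, Foxo1 by 0.69, the receptor gene Igf1r by 0.53 and Irs2 by 0.40.

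Several cell-type lists also moved lower in dKO at day 20, with marker genes of microglia the clearest. The microglia list had 0 of 18 genes higher and 13 lower (0 and 14 adjusted over the list alone), with a median of -0.66 and adjusted p = 5.82e-09, but adjusted p = 0.0902 with an estimated correlation. Beside Fcrls, the receptor genes P2ry12 (-1.67 ± 0.14), Gpr34 (-1.5 ± 0.20; -0.86 with the unstranded column) and Cx3cr1 (-0.74 ± 0.10) fell. The myelin and oligodendrocyte list had 1 of 24 genes higher and 11 lower (1 and 11 adjusted over the list alone; median -0.34, adjusted p = 0.000118), but adjusted p = 0.69 with an estimated correlation. Ugt8a (-1.25) and Gal3st1 (-0.73), which encode enzymes of myelin galactolipid synthesis, fell, as did the carbonic anhydrase gene Car2 (-1.18) and Enpp6 (-0.77). The choroid plexus list had 0 of 17 genes higher and 11 lower (0 and 12 adjusted over the list alone; median -0.80, adjusted p = 0.000118), but adjusted p = 0.402 with an estimated correlation. Sostdc1 (-1.68), the potassium channel gene Kcnj13 (-1.22), Enpp2 (-1.18) and Car12 (-1.06) fell, but Kcnj13 was not called with the unstranded column (-0.17, adjusted p = 0.322). The endothelial list had 3 of 16 genes higher and 8 lower (3 and 8 adjusted over the list alone; median -0.20, adjusted p = 0.000185), but adjusted p = 0.124 with an estimated correlation. Itm2a (-1.26), the receptor genes Tek (-1.02) and Kdr (-0.64) and the lipid transfer gene Pltp (-0.87) fell. The pericyte and smooth muscle list had 1 of 12 genes higher and 7 lower (2 and 7 adjusted over the list alone; median -0.28, adjusted p = 0.00195), but adjusted p = 0.257 with an estimated correlation. Rgs5 (-1.29), Myl9 (-0.87), Higd1b (-0.80) and Vtn (-0.32) fell, but Higd1b moved as far as -0.44 among the alternatives and Vtn lost its call in 1 of 27. The meningeal fibroblast and matrix list had 1 of 16 genes higher and 10 lower (1 and 11 adjusted over the list alone; median -0.36, adjusted p = 0.000185), but adjusted p = 0.34 with an estimated correlation. Lum (-2.20), the collagen gene Col3a1 (-1.79) and Bgn (-0.74) fell, while Mgp rose by 1.12. The proliferation list had 1 of 22 genes higher and 6 lower (0 and 6 adjusted over the list alone; median -0.66, adjusted p = 0.0023), but adjusted p = 0.711 with an estimated correlation. Beside Mki67 and Top2a, Cenpf (-1.77) and Ccnb2 (-1.05) fell.

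**Figure D3:**
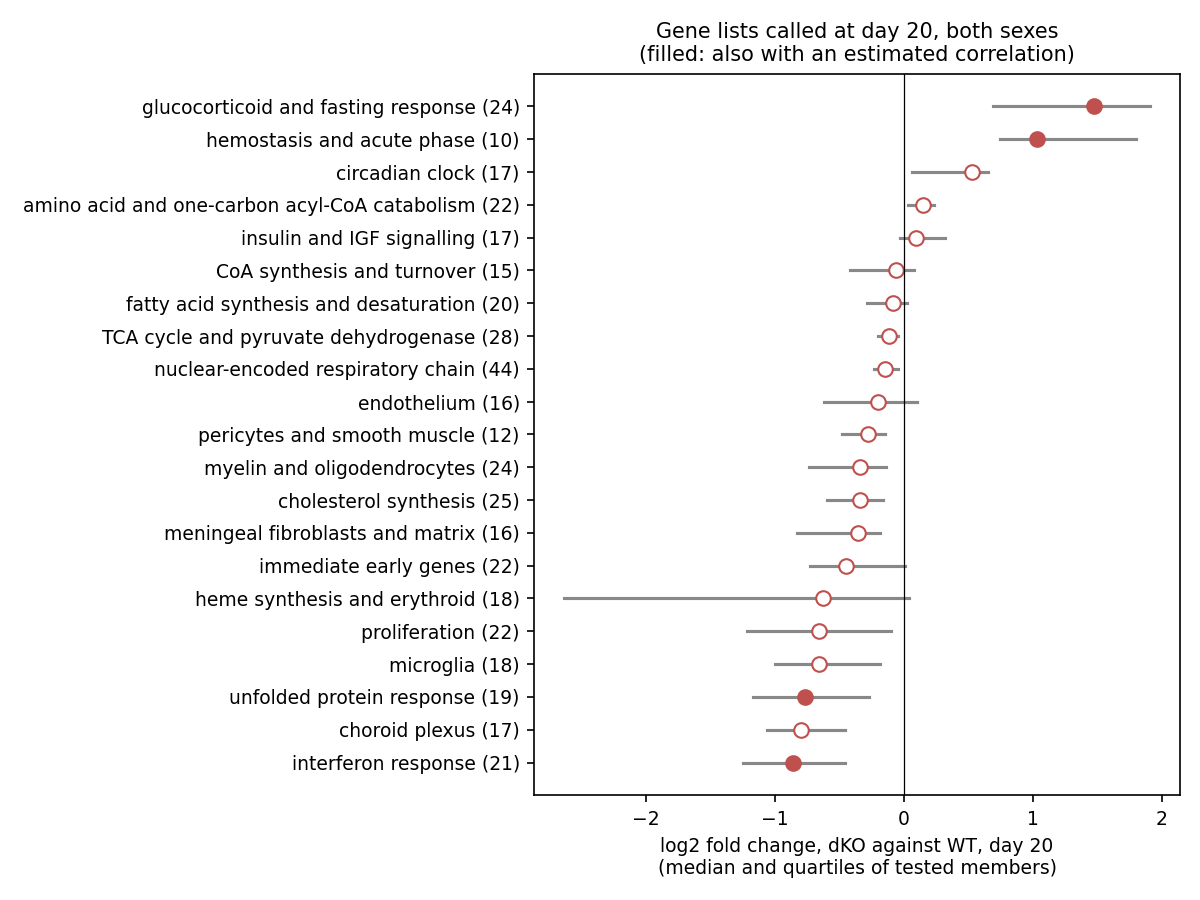
Median (point) and quartiles (line) of the log2 change of dKO against WT at day 20 over each of the 21 lists called with the preset correlation. Filled points mark the 4 lists also called with an estimated correlation, of which 2 rose and 2 fell.

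Other lists tied to iron, mitochondria and neurons were not called at day 20. They included iron handling (8 of 29 genes higher and 8 lower, adjusted p = 0.928), mitochondrial fatty acid oxidation (3 of 22 higher and 7 lower, 0.387), PPAR-alpha targets and ketogenesis (8 of 18 higher and 4 lower, 0.135) and the mitochondrial-encoded mRNAs (0 of 12 higher and 4 lower, 0.0945). The integrated stress response list had 5 of 28 genes higher and 11 lower (0.376), the NRF2 list 4 of 19 higher and 7 lower (0.182), and the p53 list 9 of 16 higher and 2 lower (0.134). Purkinje cell markers had 0 of 16 genes called in either direction (edgeR; list adjusted p = 0.928), and midbrain dopaminergic markers had 2 of 16 higher and 3 lower (0.92). Cerebellar granule cell markers had 2 of 16 higher and 1 lower (0.872). The acyl-CoA thioesterase list had 3 of 14 genes higher and 3 lower (0.928), with a median of 0.04 and a mean of 0.15 while its test pointed down. Reactive astrocyte markers had 9 of 21 higher and 7 lower (0.34), with a median of -0.01 while the test pointed up.

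Day 20 was also compared within each sex, since the design asks about females and males separately. In females, Matn1, Fkbp5 and Ada rose, and Pank1, Fcrls and Cd93 fell. Matn1 rose by 6.06 ± 0.23 (adjusted p = 2.08e-14) and Fkbp5 by 2.12 ± 0.14 (adjusted p = 1.61e-09) on the log2 scale. Ada (chromosome 2, 163726584 to 163750239), which encodes adenosine deaminase, was at 5.56 ± 1.15 CPM in dKO females against 0.449 ± 0.0535 in WT females (n = 3 each; log2 3.63 ± 0.25, adjusted p = 2.03e-09; log2 1.98 with the unstranded column). Pank1 (-1.57), Fcrls (-2.21 ± 0.18) and the endothelial receptor gene Cd93 (-1.30 ± 0.11) fell. In all, 2223 genes were called in females, 1141 higher and 1082 lower, and 481 of them changed more than 2-fold. Calls numbered 639 in DESeq2 and 4010 when only the groups compared were fitted. They numbered 1037 without WT female day 20 replicate 1, 1094 without dKO female day 20 replicate 1 and 1307 without WT female day 20 replicate 2.

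In males at day 20 the rising genes with the smallest p were Matn1, Hif3a and the collagen gene Col5a3, and the falling ones Fcrls, Pank1 and the membrane protein gene Itm2a. Matn1 rose by 6.34 ± 0.24 and Hif3a by 2.67 ± 0.16. Col5a3 was at 46.9 ± 4.54 CPM in dKO males against 12.4 ± 0.937 in WT males (n = 3 each; log2 1.92 ± 0.12). Fcrls was at 0.837 ± 0.281 CPM against 10.5 ± 1.84, a log2 change of -3.66 ± 0.21. Itm2a (-1.66 ± 0.12) and Pank1 (-1.62) fell. In all, 7450 genes were called in males, 3735 higher and 3715 lower, and 1571 changed more than 2-fold. Calls numbered 3759 in DESeq2 and 3596 when a change above 1.2-fold was required.

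Females and males were then set side by side at day 20. Both sexes called 1873 genes, 962 higher in both and 911 lower in both, where 203 and 191 were expected by chance, and 0 were called in opposite directions. Counted as genes called in the same direction in both sexes separately, day 20, they numbered 583 in DESeq2, 491 when a change above 1.2-fold was required, 3967 in voom with quality weights and 2929 with the scores of the granule cell and Hox lists fitted. Of the 2223 genes called in females, 2175 (97.8%) had the same sign in males. Across all tested genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.668 and Spearman's rho = 0.607. A test of the difference between the sexes called 0 genes at day 20 in edgeR, with 3066 at an unadjusted p under 0.05, and 0 in DESeq2 and in limma-voom. It called 1091 genes when only the day 20 groups were fitted. It called 168 without dKO male day 20 replicate 2, 14 without dKO female day 20 replicate 1, 4 without dKO male day 20 replicate 3 and 1 without WT male day 20 replicate 3. The size of change did differ: the mean change over the 8188 called genes, signed by the direction of their call, was 0.41 in females and 0.65 in males, a difference of 0.25 (exact permutation of sex within genotype, two-sided p = 0.01, where 0.005 was the smallest p possible). For 6673 of the 8188 genes the change was larger in males. Microglial markers changed on average by -0.39 in females and -1.07 in males, and interferon genes by -0.39 and -1.19 (exact permutation p = 0.005 each, adjusted p = 0.05 over the lists, which did not pass). At the same exact permutation p, 3 lists had opposite signs in females and males: mitochondrial-encoded mRNAs (0.13 and -0.44), striatal projection neurons (0.19 and -0.19) and hindbrain Hox (0.36 and -0.31).

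At day 10 the comparison of dKO with WT over both sexes asked which transcripts already differ at the earlier day. Myelin genes such as Myrf, Fa2h, Gjb1 and Cnp were lower. Neuropeptide and striatal genes such as Pdyn, Tac1 and Drd1 were higher. Each of these 3 lists had adjusted p = 0.675 with an estimated correlation, and the genes called at day 10 numbered 16 rather than 1300 without dKO male day 10 replicate 2. The greatest rises were those of the processed pseudogenes Gm13394 and Gm11942, the predicted gene Gm9008 and the noncoding RNA gene Gm16092. The glucocorticoid and unfolded protein response genes that stood out at day 20 were not called at day 10 (edgeR; 0 of 24 and 0 of 19 over all genes tested).

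In all, 1300 genes were called at day 10 (6.19%), 831 higher and 469 lower, and 111 changed more than 2-fold. The count rested on single libraries: among dKO it was 16 without male replicate 2, 4585 without male replicate 1, and 2161, 193 and 300 without female replicates 1, 2 and 3 of day 10. Among WT it was 622 and 710 without female replicates 1 and 2, and 109 and 2537 without male replicates 1 and 3 of day 10. dKO male day 10 replicate 2 stood apart from the 10 other day 10 libraries with usable depth: 11 of the 50 list scores lay below and 11 above all of theirs. Its mean log2 CPM over cerebellar granule cell markers was 5.66, against 6.30 to 7.90 in the others. Its score over the hindbrain Hox list was -0.97, against -0.03 to 3.50, that over choroid plexus markers 1.2, against 2.59 to 3.40, and that over neuroblast markers 4.58, against 5.60 to 6.37. Its scores were above all others for the list of synaptic and neuropeptide growth factors (3.58, against 2.63 to 3.31), striatal projection neurons (4, against 3.1 to 3.73) and ependyma and cilia (1.97, against 0.82 to 1.58), which are 3 of the lists called higher at day 10.

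Gm13394 was at 29.0 ± 18.9 CPM in dKO (n = 5) against 0.161 ± 0.0844 in WT (n = 6) at day 10 (log2 7.29 ± 0.79, adjusted p = 6.02e-05), with 25.5 to 46.7 CPM in 4 dKO libraries but 0.0562 in dKO male day 10 replicate 2. Gm9008 was at 3.18 ± 1.12 CPM against 0.0558 ± 0.0414 (log2 5.66 ± 0.66, adjusted p = 4.54e-05). Gm16092, a noncoding RNA gene (chromosome 1, 85511133 to 85527161), was at 2.45 ± 0.809 CPM against 0.225 ± 0.136 (log2 3.32 ± 0.35, adjusted p = 1.4e-05). Gm11942, a processed pseudogene (chromosome 4, 32964888 to 32965232), was at 8.93 ± 4.28 CPM against 1.07 ± 0.45 (log2 3.18 ± 0.24, adjusted p = 1.36e-08), with 16.5 CPM in dKO male day 10 replicate 2. Reads of these pseudogenes may be shared with near-identical copies. The processed pseudogene Gm11868 rose by 2.43, the purinergic receptor gene P2rx2 by 1.51, the dendritic protein gene Ddn by 1.36 and the ciliary gene Deup1 by 1.31 (adjusted p = 0.0102 to 0.0327), but Gm11868 lost its call in 14 of 26 alternatives, Ddn in 12 of 26 (down to 0.22), P2rx2 in 9 of 25 and Deup1 in 6 of 25 (down to 0.55). Among lower genes were Jaml (-1.54), the small heat shock protein gene Cryab (-1.21; 6.75 ± 2.72 CPM against 15.5 ± 6.07), Abcc12 (-1.17), Cdh15 (-1.17), Sp7 (-1.15), Rhbdf2 (-1.12) and Gm12122 (-1.09). Of 26 alternatives, Gm12122 lost its call in 19 (to -0.30), Rhbdf2 in 18 (to -0.16), Jaml in 14 (to -0.69), Sp7 in 12, Abcc12 in 10 (to -0.43), and Cdh15 (to -0.40) and Cryab in 9 each. Gm13394 lost its call in 2 of 26, Gm9008 in 1 of 26, Gm16092 in 1 of 25 and Gm11942 in 0 of 26. The call of the Y-linked gene Kdm5d (-1.37, adjusted p = 0.0425) was lost in 17 of 27 alternatives. Its levels parted in females, where reads were few, with 0.0156 ± 0.0269 CPM in dKO and 0.171 ± 0.0881 in WT (n = 3 each). In males it was at 74.6 ± 0.385 CPM in dKO (n = 2) and 76.9 ± 5.09 in WT (n = 3).

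Of the 50 lists, 8 were called at day 10, and 0 of them with an estimated correlation. Leaving out 1 replicate gave 7 (without WT female day 10 replicate 3) to 14 lists (without dKO male day 10 replicate 2). The myelin and oligodendrocyte list had 0 of 24 genes higher and 12 lower (0 and 21 adjusted over the list alone), with a median of -0.55 and adjusted p = 3.56e-15, but adjusted p = 0.675 with an estimated correlation. The gap-junction gene Gjb1 (-0.76), the lipid hydroxylase gene Fa2h (-0.72), Cnp (-0.51) and the transcription factor gene Myrf (-0.48) were lower, but Gjb1 lost its call in 11 of 26 alternatives, Cnp in 11 of 27, and Fa2h and Myrf in 6 of 27 each. The list of synaptic and neuropeptide growth factors had 4 of 16 genes higher and 0 lower (10 and 1 adjusted over the list alone; median 0.47, adjusted p = 0.000202), but adjusted p = 0.675 with an estimated correlation. Tac1 and Pdyn, which encode neuropeptide precursors, were higher by 0.82 and 0.78, Nptx2 by 0.60 and Adcyap1 by 0.56. Each lost its call without dKO male day 10 replicate 2, Tac1, Pdyn and Adcyap1 did so in 8 of 26 alternatives and Nptx2 in 15, and Nptx2 turned to -0.12 with 1 surrogate variable. The striatal projection neuron list had 5 of 17 genes higher and 0 lower (9 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.00078), but adjusted p = 0.675 with an estimated correlation. The dopamine receptor gene Drd1 was higher by 0.70 and the signalling regulator gene Rgs9 by 0.43, but each lost its call in 11 of 26 alternatives, among them the one without dKO male day 10 replicate 2. The cerebellar granule cell list had 0 of 16 genes called (0 adjusted over the list alone; median -0.51, adjusted p = 2.34e-05), but adjusted p = 0.751 with an estimated correlation. The Purkinje cell list had 0 of 16 genes called (1 higher and 12 lower adjusted over the list alone; median -0.56, adjusted p = 4.37e-05), but adjusted p = 0.751 with an estimated correlation. The test of the Purkinje cell list turned direction once the scores of the granule cell and Hox lists were fitted (adjusted p = 0.456). The clock list had 0 of 17 genes higher and 1 lower (1 and 2 adjusted over the list alone; median -0.16, adjusted p = 0.015, but adjusted p = 0.751 with an estimated correlation), the lower gene being Nr1d1 (-0.40; call lost in 8 of 27 alternatives). The heme and erythroid list had 0 of 18 higher and 1 lower (0 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.015, but adjusted p = 0.675 with an estimated correlation), the lower gene being Cpox (-0.33; call lost in 10 of 27 alternatives). The ependyma and cilia list had 0 of 14 genes called (6 higher and 1 lower adjusted over the list alone; median 0.41, adjusted p = 0.0153), but adjusted p = 0.751 with an estimated correlation. The hindbrain Hox list was not called, and its median of 0.27 and mean of 0.16 were above 0 while its test pointed down.

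**Figure D4:**
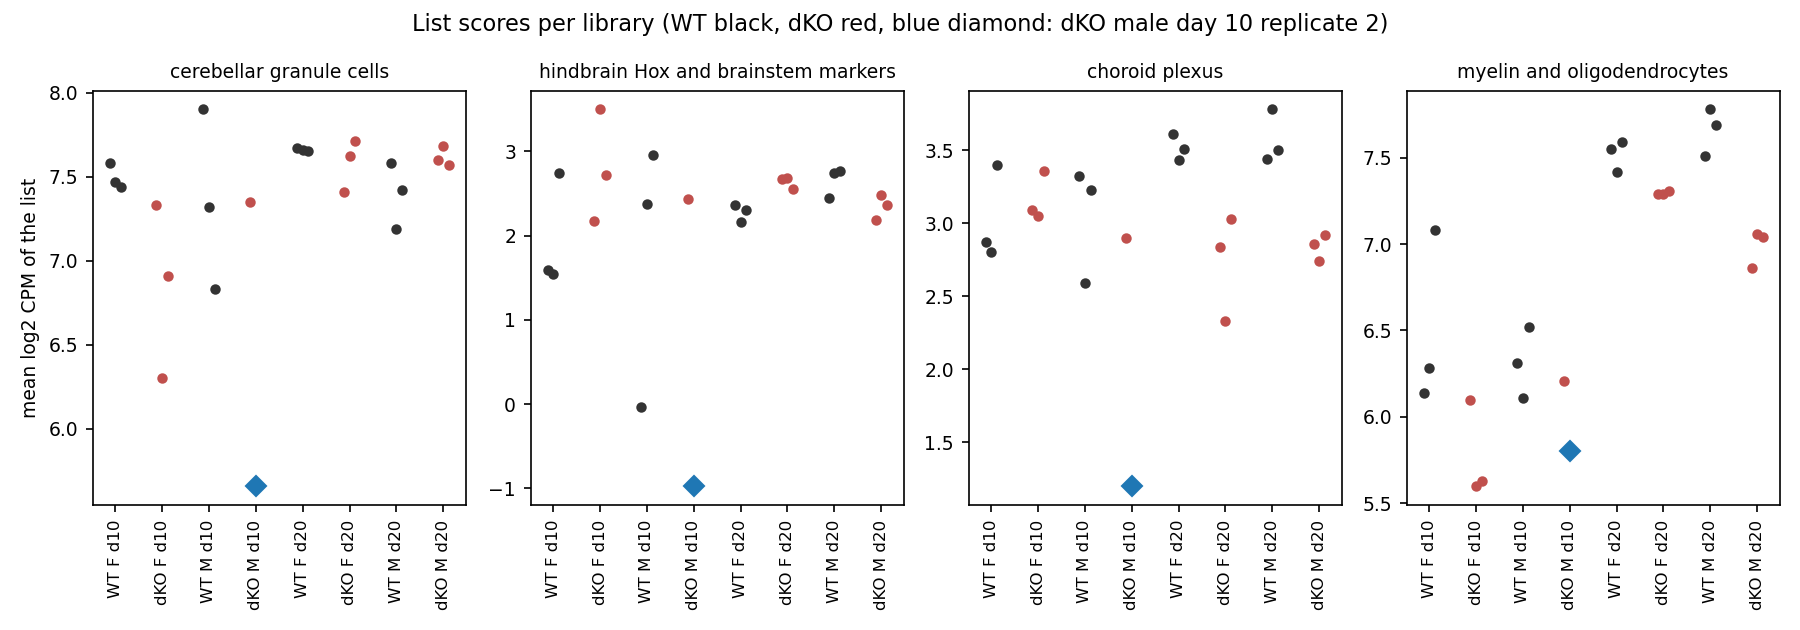
Score of 4 lists (cerebellar granule cells, hindbrain Hox, choroid plexus, myelin) in each library, as mean log2 CPM over the list. The blue diamond is dKO male day 10 replicate 2, which lies below every other day 10 library in the granule cell, Hox and choroid plexus scores.

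Within females at day 10, Pank1, Ide and Zkscan3 fell, and the pseudogenes and predicted genes Gm13394, Gm9008 and Gm11942 rose. Pank1 fell by 1.49 ± 0.11 (adjusted p = 5.06e-09). Ide (chromosome 19, 37268743 to 37337852), which encodes insulin-degrading enzyme and lies within 5 Mb of Pank1, was at 106 ± 0.721 CPM in dKO females against 198 ± 25 in WT females (n = 3 each; log2 -0.90 ± 0.13, adjusted p = 0.00242). The zinc-finger gene Zkscan3 was at 84.4 ± 15.7 CPM against 136 ± 9.33 (log2 -0.69 ± 0.10, adjusted p = 0.00187). Gm13394 rose by 8.48, Gm9008 by 5.71 and Gm11942 by 3.30. Gm9008 lost its call in 2 of 20 alternatives, Gm13394 in 1 of 20 and Zkscan3 in 2 of 21, and Pank1, Ide and Gm11942 in none. In all, 136 genes were called in females, 66 higher and 70 lower, and 27 changed more than 2-fold. The count was 1497, 10 and 13 without dKO female day 10 replicates 1, 2 and 3, and 279 and 5 without WT female day 10 replicates 1 and 3. It was 8 when a change above 1.2-fold was required.

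Within males at day 10, Pank1 and Ide were again lower, and Gm11942 and the noncoding RNA gene Gm16092 were higher. Pank1 (-1.43, adjusted p = 2.59e-07) and Ide (-0.77, adjusted p = 0.0453) fell. Gm11942 rose by 3.06 (adjusted p = 2.25e-05), Gm16092 by 3.66 (adjusted p = 0.00305) and Gm48755 by 1.29 (adjusted p = 0.0453). The uncharacterised A730094K22Rik fell by 2.34 (adjusted p = 0.0453), to 0.589 ± 0.118 CPM in dKO males (n = 2) against 2.89 ± 0.708 in WT males (n = 3). Not all of these calls held: Ide lost its call in 16 of 21 alternatives, A730094K22Rik in 15 of 21, Gm48755 in 14 of 21 and Gm16092 in 6 of 19, while Pank1 lost it in 1 and Gm11942 in 2. In all, 24 genes were called, 19 higher and 5 lower, and 16 changed more than 2-fold. The group of dKO males held 2 libraries of usable depth, and the count was 4303, 3 and 3 without dKO male day 10 replicates 1, 2 and 3. It was 2, 4 and 805 without WT male day 10 replicates 1, 2 and 3. Both sexes called 8 genes at day 10, 5 higher and 3 lower, and across genes the log2 changes of the sexes correlated with r = 0.29 and rho = 0.267. The test of the difference between the sexes called 0 genes in edgeR, with 2449 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom, but in edgeR 1920 without dKO male day 10 replicate 1 and 12 without dKO female day 10 replicate 1.

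Whether the genotype effect differed between the days was tested directly. The microglial gene Fcrls, the endothelial gene Cd93, Matn1, Fam214a and Scrg1 had the smallest p among genes whose effect changed. Fcrls was at 14.6 ± 2.05 CPM in dKO and 12.3 ± 1.03 in WT at day 10, and at 1.51 ± 0.901 and 10.1 ± 1.34 at day 20, a change in effect of -3.22 ± 0.18 on the log2 scale (adjusted p = 6.76e-12). Matn1 was at 0.423 ± 0.0733 and 0.382 ± 0.11 CPM at day 10, and its effect changed by 6.10 ± 0.44. Cd93 was at 54.3 ± 5.64 and 48.1 ± 3.78 CPM at day 10 and at 10.7 ± 1.41 and 26.7 ± 2.17 at day 20 (-1.48 ± 0.11). Scrg1 went from 9.33 ± 1.31 and 10.9 ± 1.15 CPM to 35.0 ± 4.51 and 12.2 ± 0.543 (1.74 ± 0.14). Fam214a went from 66.4 ± 7.27 and 77.8 ± 4.57 CPM to 201 ± 19.3 and 93.8 ± 9.58 (1.31 ± 0.08). In all, 6016 genes differed in effect, 2916 toward a higher and 3100 toward a lower effect at day 20; the count was 2601 in DESeq2 and 2197 when a change above 1.2-fold was required. Of the 462 genes called in both day comparisons, 113 were higher at both days, 226 moved in opposite directions and the rest were lower at both days, where 161 higher and 91.7 lower were expected by chance. These counts rest on the 1300 calls of day 10, a comparison that called 16 genes without dKO male day 10 replicate 2. Across genes the log2 changes of the days correlated with r = 0.0711 and rho = 0.00731.

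WT libraries of day 20 were compared with those of day 10 to give the background of age. Lists of myelin genes moved higher, and lists of proliferation and of immature neuron genes lower, but with adjusted p = 0.392, 0.089 and 0.089 with an estimated correlation. The astrocyte enzyme gene Etnppl rose from 1.30 ± 0.772 to 50.6 ± 8.44 CPM (n = 6 each; log2 5.12 ± 0.27). The calcium-binding protein gene Cabp2 rose by 3.02, and the uncharacterised Gm19439, Gm39465 and 2900052N01Rik by 3.40, 3.30 and 3.14. Igfbpl1 fell from 58.3 ± 13.9 to 0.483 ± 0.273 CPM (log2 -6.83 ± 0.51), and the neuronal transcription factor genes Atoh1 (-6.12) and Nhlh1 (-5.75) fell too. Nhlh1 was at 10.5 ± 2.03 CPM at day 10 and 0.193 ± 0.0996 at day 20. A730004F24Rik (-6.16) and the histone gene Hist1h2ah (-5.73) fell. The myelin list had 22 of 24 genes higher and 0 lower (22 and 1 adjusted over the list alone; median 1.2, adjusted p = 2.66e-11), but adjusted p = 0.392 with an estimated correlation. Hapln2 rose by 2.25, Aspa by 1.77, Car2 by 1.16 and Myrf by 0.90. The proliferation list had 0 of 22 genes higher and 22 lower (0 and 22 adjusted over the list alone; median -3.48, adjusted p = 8.54e-27), but adjusted p = 0.089 with an estimated correlation. Aurkb (-4.88), Ccnb1 (-4.86), Cenpe (-3.71) and Rrm2 (-3.24) fell. The list of neuroblasts and immature neurons had 1 of 18 genes higher and 15 lower (1 and 15 adjusted over the list alone; median -2.11, adjusted p = 6.08e-21), but adjusted p = 0.089 with an estimated correlation. The tubulin gene Tubb2b (-2.68), Sox4 (-2.14), Marcksl1 (-1.82) and Mex3b (-1.80) fell. In all, 10858 genes (51.7%) were called, 5511 higher and 5347 lower at day 20; the count was 7230 in DESeq2 and 5746 when a change above 1.2-fold was required.

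WT males were compared with WT females to give the background of sex. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y were higher by 9.30, 9.34, 9.35 and 9.26 on the log2 scale in males, and Xist was lower by a log2 change of -9.98. The X-linked Eif2s3x was at 49.0 ± 3.77 CPM in males and 67.6 ± 5.94 in females (n = 6 each; log2 -0.46 ± 0.05, adjusted p = 6.75e-06). The Y-linked noncoding genes and pseudogenes Gm29650, Gm18665, Gm4017 and Tspy-ps were at 3.31 ± 0.447, 0.929 ± 0.236, 0.478 ± 0.168 and 0.490 ± 0.177 CPM in males, with 0 to 0.00363 CPM on average in females, and their reads may be shared with near-identical copies. In all, 16 genes were called, 10 higher and 6 lower in males; the count was 25 without WT female day 10 replicate 3 and 9 when a change above 1.2-fold was required.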

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

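Choices of comparisons, tests, lists and the rule for naming genes were made before the data were examined. Among the tests here, drawing libraries down in depth at day 20 and the axis of tissue age at day 10 were set before their results were seen, and those of the total of a single library, regional share, cell-type share, shared reads, nearness to Pank1 and Pank2, and regrouped samples were chosen only after the result was seen.

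The genotype effect differed between the days for 6016 genes. The microglial gene Fcrls (change in effect -3.22 on the log2 scale) and the endothelial gene Cd93 (-1.48) went lower in dKO between the days, and Matn1 (6.10), Scrg1 (1.74) and Fam214a (1.31) went higher. The size of the day 20 change also differed between the sexes, with a signed mean that was 0.25 higher in males than in females. Drawing every deeper library down to 15.9 M counts left 7232 genes called at day 20, of which 6988 were called at full depth, which argues against a difference in depth as the source of the day 20 change. With the scores of the granule cell and Hox lists as covariates 9616 genes were called. Between dKO and WT the Hox score differed by 0.36 in females and -0.31 in males, and the granule cell score by -0.08 and 0.22. Fitting scores with opposite signs in the sexes could remove little of a change averaged over both. No other pairs of lists were tried at day 20, so this cannot decide on a different share of these regions. Of 9 glial, vascular and barrier lists 6 were lower at the preset correlation and 0 higher, and 1 had a median within 0.1 of 0; 0 of the 6 passed with an estimated correlation (adjusted p = 0.0902 to 0.69). Single genes fell in 13 of 18 for microglia and 11 of 17 for choroid plexus, with 0 higher in either. Each of the other lower lists held at least 1 gene called higher, and 39.0% of all genes tested were called. Members of a list can vary together, and loss of a small cell type would raise other markers by little. These counts therefore cannot decide on a lower share of 1 cell type. A change in expression within cells, a lower share of 1 cell type, a change in the share of several, and a different share of brain regions remain open as hypotheses.

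The day 10 calls rested on dKO male day 10 replicate 2: 1300 genes were called with it and 16 without it. Its total of 17.5 M counts lay within the range of the other day 10 libraries, which argues against low depth. On an axis from WT day 10 (0) to WT day 20 (1) the library lay at 0.19, under the bound of 0.25 set before. By that rule alone the value went against older tissue. It was under the bound by less than the SD of WT day 10 libraries (0.113), a margin that was not part of the rule set before. The library lay beside WT female day 10 replicate 3 at 0.192 and above the 4 other dKO libraries (-0.253 to -0.016). Its proliferation score (2.98, others 3.59 to 5.13) and neuroblast score (4.58, others 5.60 to 6.37) were lower, as in older WT. Its myelin score (5.8, others 5.6 to 7.08) and interferon score (1.23, others 0.98 to 1.52), which rise with age in WT, lay within the range of the others. With that margin and these mixed scores, older tissue stays open. A different share of brain regions in the dissected piece cannot be told apart from other differences of this library: with the regional scores as covariates 14 genes were called, but 20 other pairs of lists gave 1 to 4047 calls (median 70), and 7 of them gave 14 or fewer. No biological explanation was tested, since the labels give none for a single library.

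Without that library and the library of 45964 counts, 16 genes were called at day 10, and 11 of them besides Pank1 were called in the same direction at day 20 (the dKO male group of day 10 then held 1 library, which is assumed to vary like the other groups): Gm16092, Gm13410, Gm13394, Gm11942, Gm9008, Slc6a2, Pts, Nipsnap1, Zkscan3, Tubb4a and Ide. Of these 8 lay on chromosomes without Pank1 or Pank2, which argues against variants carried along with the targeted genes as the source of all of them. Within 5 Mb of Pank1 or Pank2 lay 1 (Ide; Fisher's exact p = 0.0939), so for Ide such variants stay open. As 3 were annotated as pseudogenes (Gm13410, Gm13394 and Gm11942; Fisher's exact p = 0.0347), reads shared with near-identical copies are a candidate source for those 3. Variants elsewhere in the genome were not tested. Gm13394 and Gm13410 lie on chromosome 2 with Pank2, but 102 and 107 Mb from it. Gm13394 was near the WT level in dKO male day 10 replicate 2, which was left out here. For the other genes an effect of the knockout, like such variants, remains open as a hypothesis.

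Single libraries lay far from the rest of their genotype and day in 10 of 98 groups of values from 43 genes, where chance gives about 5. In dKO male day 10 replicate 2, Pank3 was at 188 CPM (others 217 to 229) and Gm11942 at 16.5 CPM (others 6.45 to 7.61). In WT male day 10 replicate 1, Ddn was at 2.70 CPM (4.32 to 5.16), and in WT female day 20 replicate 3, Matn1 was at 0.744 CPM (0.170 to 0.377) and Nhlh1 at 0 (0.200 to 0.283). In WT male day 20 replicate 2, Fcrls was at 12.6 CPM (8.92 to 10.2) and Gm19439 at 21.6 CPM (13.3 to 15), and in WT female day 10 replicate 3, Gm19439 was at 2.33 CPM (1.07 to 1.35). Hbb-bt was at 6.82 CPM in dKO female day 20 replicate 1 (3.36 to 4.42), and Atoh1 at 0.209 CPM in WT female day 20 replicate 1 (0 to 0.0566).

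Regrouping the same samples tested whether chance could give as many calls. For both sexes at day 20, 1 of 100 splits (the real one) gave as many genes (8188, highest other 5301). This is the smallest share that 100 splits can give, and chance is unlikely as the source of this count. For genotype by day (6016, highest other 1530) and for WT day (10858, highest other 6170) it was also 1 of 100, and chance is likewise unlikely. For both sexes at day 10 it was 3 of 100 (1300; highest other 3431, with dKO male day 10 replicate 1 and WT male day 10 replicate 3 exchanged), a share under 0.05, but wrong splits gave more calls than the real one and 16 genes were called without dKO male day 10 replicate 2, so this points to a structure of the samples and chance is not taken as excluded. For WT sex it was 3 of 100 (16; highest other 20), also a share under 0.05 with wrong splits above the real one, and chance is not taken as excluded for this count. For the genotype by sex interactions the real count was 0, so that 100 of 100 splits gave as many by construction and chance was not tested (highest other 2215 at day 10, which points to a structure of the samples, and 42 at day 20). Chance cannot be excluded for the number of lists called at day 10 (8; 90 of 100 splits, highest other 25) and at day 20 (21; 5 of 100 splits, highest other 22). Within 1 sex the 10 splits are too few for a share under 0.05. There the real and highest other values were 136 and 1 for females at day 10 (1 split as large), 2223 and 0 for females at day 20 (1 split), 24 and 2766 for males at day 10 (3 splits, a structure of the samples), and 7450 and 1 for males at day 20 (1 split).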

How the results depend on the processing

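The settings named as added were chosen only after the data were seen; all others were planned. At day 20 over both sexes, the named genes kept their direction and their side of the threshold in 957 of 965 combinations of gene and planned setting (8 weaker), in all 1164 that left out 1 replicate and in all 485 with an added setting. The called lists of day 20 did so in 88 planned combinations (17 weaker), 241 that left out 1 replicate (11 weaker) and all 84 added. Most of these genes were named for a great change or a small p in the planned test of the same data, and the lists for passing it. High shares follow in part from that choice and do not describe all called genes. At day 10 over both sexes, named genes were the same in 364 planned combinations, weaker in 93, stronger in 12 and reversed in 1 (Nptx2, -0.12 with 1 surrogate variable). Leaving out 1 replicate gave 459 the same, 108 weaker and 33 stronger, and the added settings 169, 65 and 16. These day 10 tallies include list members that were not called. A gene called neither in the planned test nor in the alternative counted as the same even where its sign turned. Arntl (-0.57 to 0.05 over the alternatives) and Homer3 (-1.1 to 0.02) were such genes. The called lists of day 10 were the same in 23 planned combinations (17 weaker), 87 that left out 1 replicate (9 weaker) and 24 added (6 weaker, 2 reversed). Those 2 were the granule cell and Purkinje cell lists with the added regional scores (adjusted p = 0.794 and 0.456), for granule cells by construction, since the list's own score was fitted. Sizes of called genes also moved with the unstranded column at day 20, where Plin4 was at 2.71, Gm17120 at 1.72, Gm12941 at -1.39 and Kcnj13 at -0.17 (not called). The genes called in the same direction in both sexes separately, day 20, numbered 583 (DESeq2), 491 (change above 1.2-fold), 3967 (voom with quality weights) and 2929 (regional scores), against 1873. The numbers of genes called that moved by more than 1.5 times follow, with F, M and B for females, males and both sexes at the day given. RLE factors gave 3 (M10). No filter gave 74 (M10), 718 (B10) and 24 (genotype by sex at day 20), and a stricter filter gave 5 (M10). The unstranded column gave 37 (M10), and the earlier edgeR estimate 80 (F10) and 3 (M10). DESeq2 gave 639 (F20), 11 (M10), 3759 (M20), 393 (B10), 4404 (B20), 2601 (genotype by day), 1 (genotype by sex at day 10) and 7230 (WT day), and no adjusted p for Pank1 at day 10. Limma-voom gave 67 (M10). With 1 surrogate variable there were 68 (F10), 1 (M10), 22 (B10) and 3482 (genotype by day). A change above 1.2-fold, a stricter test by construction, left 8 (F10), 556 (F20), 3 (M10), 3596 (M20), 12 (B10), 2941 (B20), 2197 (genotype by day), 5746 (WT day) and 9 (WT sex). Fitting only the groups compared gave 11 (F10), 4010 (F20), 0 (M10), 9 (B10) and 1091 (genotype by sex at day 20). With the added settings, leaving out the library of 45964 counts gave 3 (M10), and leaving it out with dKO male day 10 replicate 2 gave 572 (F10), 3 (M10), 16 (B10), 119 (genotype by sex at day 20) and 14 lists at day 10. Voom with quality weights gave 2750 (F10), 5372 (F20), 2 (M10), 675 (B10), 1571 (genotype by sex at day 20) and 50 (WT sex). The surrogate variable without the library of 45964 counts gave 38 (F10), 716 (M10) and 2104 (B10), and the regional scores 23 (F10), 3512 (F20), 4 (M10), 14 (B10) and 150 (genotype by sex at day 20). An estimated correlation left 0 lists at day 10 and 4 at day 20, and fry called 3 at day 10. Leaving out 1 replicate in turn gave 5 (without WT female day 10 replicate 3) to 1497 (without dKO female day 10 replicate 1) for F10, 1037 (without WT female day 20 replicate 1) to 1838 for F20, 2 (without WT male day 10 replicate 1) to 4303 (without dKO male day 10 replicate 1) for M10, 16 (without dKO male day 10 replicate 2) to 4585 (without dKO male day 10 replicate 1) for B10, 7159 to 7771 for B20 and 5486 to 6685 for M20. It gave 0 to 1920 (without dKO male day 10 replicate 1) and 0 to 168 (without dKO male day 20 replicate 2) for genotype by sex at day 10 and day 20, 11 to 25 (without WT female day 10 replicate 3) for WT sex, and 7 to 14 lists at day 10 (14 without dKO male day 10 replicate 2). Pank1 stayed between -1.50 and -1.42 at day 10 and between -1.62 and -1.55 at day 20, and Pank2 between -0.16 and -0.05 and between -0.45 and -0.38. Where construction does not show it, the cause was not tested. No paired analysis was possible because the labels give no replicate numbers. Depth limits low genes most: 1 count is 0.0224 to 0.109 CPM in 23 libraries.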

Other observations

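The tests here, of gene families and of delayed maturation, were chosen only after the result was seen; p-values of families are adjusted over 12 families. At day 20 heat shock and cochaperone genes were lower in dKO, with 6 of 75 higher and 33 lower (median -0.15, adjusted p = 2.64e-07), but adjusted p = 0.13 with an estimated correlation. Hspa1b, which encodes an inducible Hsp70 (log2 change -2.32), Hsph1 (-1.35) and the Hsp90 cochaperone gene Chordc1 (-0.76) fell. Mitochondrial ribosomal proteins had 7 of 74 higher and 32 lower (median -0.12, adjusted p = 0.00303), but adjusted p = 0.75 with an estimated correlation, with Mrpl36 at -0.77, Mrpl24 at -0.39 and Mrpl41 at 0.62. Protocadherins, neuronal adhesion genes, had 18 of 56 higher and 0 lower but did not pass as a family (median 0.11, adjusted p = 0.0836). Collagens had 5 of 44 higher and 16 lower (adjusted p = 0.0766), with Col5a3 at 1.72 and Col3a1 at -1.79. Among solute carriers, 67 of 274 were higher and 59 lower, and the iron exporter gene Slc40a1 (-1.01) and the cystine transporter gene Slc7a11 (-1.12) fell.

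At day 10 cytosolic ribosomal proteins had 13 of 81 genes higher and 0 lower in dKO (median 0.15, adjusted p = 4.54e-17), but adjusted p = 0.863 with an estimated correlation. Between day 10 and day 20 in WT they had 0 of 81 higher and 80 lower (median -0.57, adjusted p = 4.19e-42), but adjusted p = 0.0743 with an estimated correlation. Histone genes had 0 of 56 higher and 52 lower (median -2.86, adjusted p = 4.18e-35), but adjusted p = 0.0757 with an estimated correlation. Over the same days, the interferon list had 19 of 21 genes higher and 0 lower (median 1.03, adjusted p = 5.09e-07), but adjusted p = 0.089 with an estimated correlation. The unfolded protein response list had 18 of 19 higher and 0 lower (median 0.37, adjusted p = 8.18e-05), but adjusted p = 0.525 with an estimated correlation. Both of those lists were lower in dKO than in WT at day 20.

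One hypothesis was that dKO brains were delayed in maturation at day 20. Across genes, the WT day effect in females and the dKO effect at day 20 in males correlated with r = 0.01 (rho = 0.01), and 1459 of 2993 genes called in both (48.7%) moved in opposite directions, which argues against a general delay across genes as the source of the change in males. The WT day effect in males and the dKO effect in females correlated with r = -0.06 (rho = -0.11), and 654 of 1072 genes called in both (61.0%) moved in opposite directions, so a partial delay in females stays open. A delay limited to some genes stays open in males too. The myelin (mean -0.67), interferon (-1.19) and unfolded protein response (-0.84) lists, higher with age in WT, were lower in dKO males. Against a delay, the proliferation (-0.84) and neuroblast (-0.08) lists, lower with age in WT, were not higher. On the axis from WT day 10 (0) to WT day 20 (1), the dKO libraries of day 20 lay at 0.949 to 0.971 and the WT libraries at 0.967 to 1.02. The WT libraries set this axis and its genes, so those of day 20 average 1 by construction. The gap between the ranges therefore cannot decide on a delay at day 20. A delay at day 10 was not tested. On this axis 4 dKO libraries of day 10 lay at -0.253 to -0.016 and dKO male day 10 replicate 2 at 0.188. WT libraries of day 10, which average 0 by construction, lay at -0.083 to 0.192. The myelin list, lower in dKO at day 10, was higher with age in WT, and cytosolic ribosomal proteins, higher in dKO, were lower with age.

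Within 5 Mb of Pank1, 9 of 59 tested genes were called at day 10 (15.3%, against 6.16% elsewhere; Fisher's exact p = 0.00991) and 25 of 59 at day 20 (42.4%; p = 0.595). The day 10 share rests on the 1300 calls that became 16 without dKO male day 10 replicate 2. With that library and the library of 45964 counts left out, only Ide besides Pank1 was called near Pank1. Within 5 Mb of Pank2, 6 of 126 were called at day 10 (Fisher's exact p = 0.709) and 50 of 126 at day 20 (p = 0.927). The leading principal components of 23 libraries held 50.8 and 11.3% of the variance of log2 CPM.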
